A study of Saccharomyces cerevisiae with 36 samples.

How the data were processed

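RNA levels were measured in 36 yeast samples, of which 32 are strand-specific RNA-seq libraries and 4 are CAGE samples. Of the RNA-seq libraries 24 are rRNA-depleted (12 groups of 2) and 8 were treated with Terminator (4 groups of 2). Per the labels' protocols, total RNA was extracted with hot phenol, depleted of rRNA with RiboMinus beads or digested with Terminator 5'-phosphate-dependent exonuclease, and made into stranded paired-end libraries for a HiSeq 2500. The CAGE cultures of wild type and dcp2-7 were moved to 37 °C for 2 h, per the labels' protocols. Per the submitters' processing notes, TopHat, cutadapt and Bowtie were used, and their versions are not given in the sources used here. The genome build is not given either.

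The deposited RNA-seq table holds a signal per feature and library, which the authors named a density in the column names. It was read here as reads per nucleotide times one factor per library, because density times length came out as whole multiples of one value in 100% of values (tolerance 0.01). Density times length summed over the 77 snoRNAs was also equal in all libraries. The design foresaw a count test only for counts, and since the file held densities, its limma branch was used. The CAGE data were deposited as single-nucleotide positions, one list per genotype pooled over its replicates, and hold no score or height. The Terminator columns of wild type and xrn1 at no stated temperature leave out the background name and were assigned to S288C from the sample titles, as no other samples fit. Coordinates are those of the deposited table. Of 5798 genes 5789 matched the yeast reference annotation R64 by name, 5757 of them with the same coordinates, and symbols come from that annotation.

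The table has 9765 features: 5798 genes (called mRNAs here), 3570 lncRNAs (1798 XUTs, 925 CUTs, 847 SUTs), 299 tRNAs, 77 snoRNAs, 15 other ncRNAs and 6 snRNAs. Of the lncRNAs 2157 overlap an annotated mRNA on the other strand by at least 1 nt and 1863 by at least 200 nt, while 1655 overlap another lncRNA on the same strand and so share reads with it.

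Values were taken as log2 of the density plus a pseudocount, the 5th percentile of non-zero densities (0.00576637 for the rRNA-depleted libraries and 0.0084084 for the 16 libraries of the Terminator model). Features at or above it in at least 2 libraries were tested, 9712 and 9615 of them. One linear model per set was fitted with limma 3.58.1 in R 4.3.3 (trend and robust empirical Bayes, 12 and 8 residual degrees of freedom). Tests are two-sided, adjusted with Benjamini-Hochberg, and a feature rose, fell or changed at an adjusted p under 0.05. Standard errors are the moderated ones, and SDs are between the 2 replicates of a group. Differences between strains and between Terminator responses are interaction terms of the same models. The labels give no pairing of replicates, so none was modelled. The correlation of replicate deviations between mutant and wild type lay between -0.0707 and 0.0600, and that between the untreated and Terminator libraries of a strain between -0.163 and 0.268. Pairing by replicate number was run as an alternative.

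Gene lists were fixed before the data were examined and compared with the other mRNAs by camera, limma's competitive test, with a preset correlation of 0.01 between genes and again with an estimated one. Camera p-values were adjusted over the 16 lists of a comparison. The lists were NMD factors, reported NMD targets, decapping and decay factors, exosome and Nrd1 complex, ribosomal proteins, histones, heat shock chaperones, general stress genes, glycolysis, oxidative phosphorylation, amino acid biosynthesis, the phosphate regulon, auxotrophic markers, alpha-cell genes, mating type and pheromone genes, and meiosis genes. Examples from a list are up to 4 members with the smallest adjusted p.

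Named features follow a rule. Each comparison names the targeted gene, then features with an adjusted p under 0.05, a change of at least 2-fold, both mutant libraries beyond both wild-type libraries, and a mean above the median of their class. Of these the 6 mRNAs and 6 lncRNAs with the largest rise are named, with 6 mRNAs and 3 lncRNAs with the largest fall, or as many as pass. For W303 and both SK1 comparisons 3 mRNAs are named each way. For Terminator the 5 lncRNAs and 3 mRNAs with the largest fall are named, and for strain differences the 5 largest in size. For CAGE the rule needed a peak score, so lncRNAs with the largest dcp2-7 change were named instead, a choice made after the lists were seen.

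CAGE positions were matched to features by strand with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, within 50 nt of a 5' end. For their location, positions up to 200 nt upstream of an mRNA or inside one were assigned to it first. Of the others, those inside a lncRNA or within 50 nt of it were assigned to lncRNAs. Proportions have 95% Wilson intervals. Figures were drawn with matplotlib 3.10.9.

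The scripts were tested on simulated data made for each comparison with 200 changed features. For xrn1 S288C, 96.0% of 4-fold and 79.0% of 2-fold changes were recovered with 15 false calls among 9510 features (7.89% of its calls). For W303 the false calls were 155 among 9511, which was 48.0% of its calls. All simulated groups shared a dispersion of 0.00513, and mutant means equalled wild type except at the changed features. The real groups varied unequally, with a chi-square of replicate reads per degree of freedom from 2.96 (xrn1_W303) to 60.1 (WT_SK1_2n). The simulated rates may thus not carry over to these data. Alternatives tried were other pseudocounts, filters and scalings, models of fewer groups, a replicate block, an estimated correlation, other overlaps and windows, and leaving out each library. Added after the data were seen were voom on recovered reads, leaving out lncRNAs that overlap on one strand, leaving out chromosome 11, and matching CAGE positions within 10 nt.

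With 11021562 to 68466587 reads on features per rRNA-depleted library and 2 replicates per group, changes near the floor rest on few reads, and reads are given where a group had 1 to 3 over both libraries.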

Results

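The data describe how budding yeast RNA levels change when cytoplasmic RNA decay is impaired, and the series asks how far nonsense-mediated decay (NMD, a surveillance pathway that degrades RNAs with aberrant translation termination) acts on long non-coding RNAs (lncRNAs). Strand-specific RNA-seq covered cells lacking Xrn1, the cytoplasmic exonuclease that degrades RNA from the 5' end, in the backgrounds S288C, W303, haploid SK1 and diploid SK1 (SK1_2n). It also covered the temperature-sensitive dcp2-7 mutant of the decapping enzyme at 37 °C and cells lacking Upf1, the NMD helicase encoded by NAM7. Each mutant has its own wild type, which makes 12 groups of 2 rRNA-depleted libraries. A further 8 libraries, in 4 groups of 2, were made from RNA treated with Terminator, an exonuclease that digests RNAs carrying a 5'-monophosphate and spares capped RNAs. CAGE, which maps capped 5' ends, was done on 4 samples of wild type and dcp2-7 after 2 h at 37 °C. The rRNA-depleted libraries held between 11021562 and 68466587 reads on annotated features, and the Terminator libraries between 13208233 and 23350952. Replicates correlated with Pearson coefficients from 0.987 to 0.997 across features, which are not independent replicates.

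The signal is reads per nucleotide scaled to equal snoRNA reads, and all changes are log2 values with a standard error (SE), except where a mean ± SD (n = 2) is given. The lncRNAs are XUTs (Xrn1-sensitive unstable transcripts), CUTs (cryptic unstable transcripts, targets of the nuclear exosome) and SUTs (stable unannotated transcripts). XUTs were defined by their sensitivity to Xrn1, so their direction in xrn1 cells is not independent evidence. Positions are given as chromosome:start-end with the strand.

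Loss of Xrn1 in S288C raised most lncRNAs and most mRNAs relative to snoRNAs. Of 1798 XUTs, 1718 rose and 28 fell, with a median change of 2.16, and 1625 rose by at least 2-fold. This median was 2.55 with a pseudocount of 0.000576637. With one at the 25th percentile it was 1.31, below the mRNA median of 1.41. Among 839 SUTs 811 rose (median 2.31), and among 923 CUTs 792 rose (median 1.39). Of 5760 mRNAs, 5461 rose and 15 fell, with a median of 1.58. XRN1 itself (7:175527-180113, minus strand) fell by 7.43 (SE 0.142), from 1.60 ± 0.0345 to 0.00354 ± 0.000635.

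**Figure D1:**
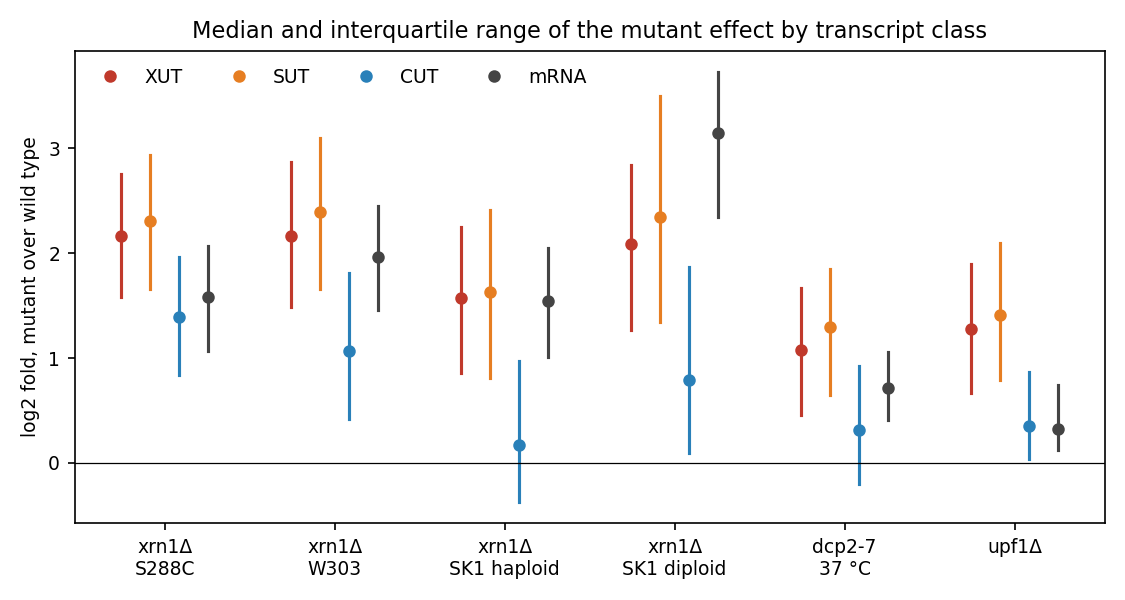
Log2 change of signal, mutant against its own wild type, by feature class for the 6 comparisons, on the scale set by snoRNA reads. With the main pseudocount, median XUT changes lay between 1.07 in dcp2-7 and 2.17 in W303, and median mRNA changes between 0.32 in upf1 and 3.14 in diploid SK1.

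The largest mRNA rises in xrn1 S288C cells were those of SNO1 (13:457285-457959, minus strand) and SNZ1 (13:458408-459301, plus strand), a divergent pair of vitamin B6 biosynthesis genes. SNO1 rose by 7.22 (SE 0.223), from 0.00492 ± 0.00152 to 1.58 ± 0.103, and SNZ1 rose by 5.63 (SE 0.196), from 0.116 ± 0.00276 to 6.05 ± 0.261. The other 4 of the 6 largest were KDX1 (11:149386-150687, minus strand; 5.37, SE 0.135), PIR3 (11:144401-145378, plus strand; 5.22, SE 0.183), SRL3 (11:611525-612265, plus strand; 4.94, SE 0.157) and FRE2 (11:9091-11226, minus strand; 4.88, SE 0.150). All 4 lie on chromosome 11, whose mRNAs rose by a median of 2.46 against 1.54 on the other chromosomes in this comparison. DDR48 (13:608689-609981, plus strand), a DNA damage and stress response gene, fell by 1.24 (SE 0.206).

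Of the lncRNAs, SUT229 (11:151135-152919, plus strand) rose by 5.63 (SE 0.154) and the overlapping XUT0575 (11:150730-152948, plus strand) by 5.56 (SE 0.150), so their reads are shared. CUT229 (11:246094-246630, plus strand), opposite APE1, rose by 5.09 (SE 0.202), from 0.0433 ± 0.000872 to 1.67 ± 0.114. SUT657 (11:21253-22197, minus strand) rose by 5.07 (SE 0.166) and SUT218 (11:18569-19681, plus strand) by 4.98 (SE 0.135). XUT0911 (16:697549-698465, plus strand), opposite YPR078C and the only one of these 6 off chromosome 11, rose by 4.99 (SE 0.205).

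Chromosome 11 stood out as a whole in this comparison. Its mRNAs rose by a median 0.92 more than those of the other chromosomes, with 310 of 311 called higher, and its lncRNAs by 2.82 against 1.96. The other chromosomes lay between -0.204 and 0.0105 of the rest. Every change given here for a chromosome 11 feature in xrn1 S288C cells carries this offset, and so do its differences from the other strains.

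**Figure D2:**
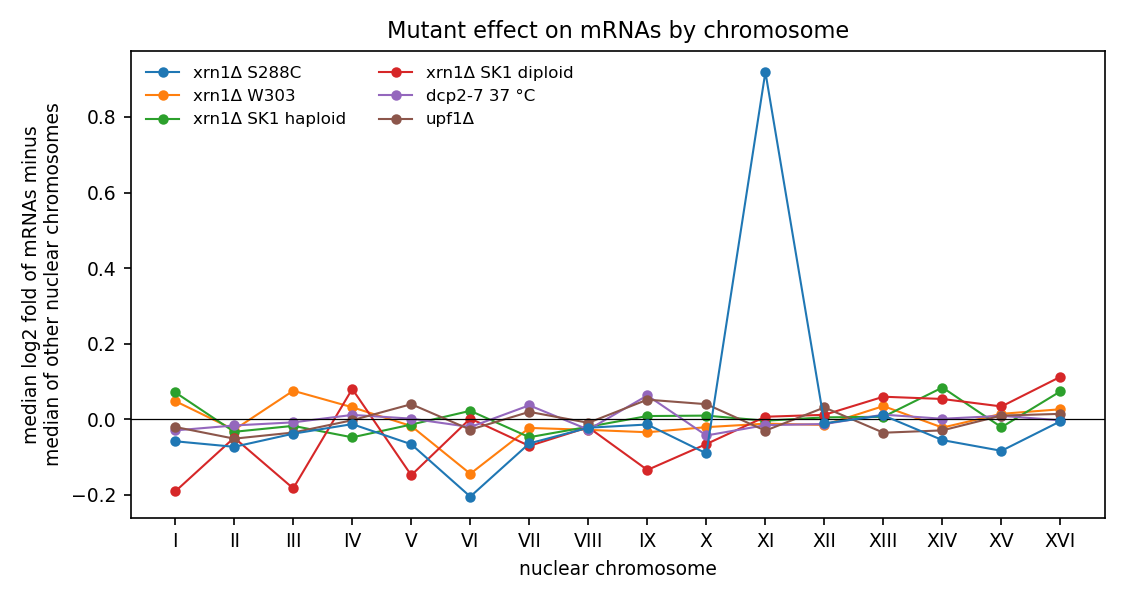
Median log2 change of the mRNAs of each chromosome in the comparisons of mutant and wild type, relative to the mRNAs of the other nuclear chromosomes. In xrn1 S288C the mRNAs of chromosome 11 had a median of 2.46 against 1.54 elsewhere.

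All 15 reported NMD target mRNAs rose in xrn1 S288C cells (median 2.27), and 11 rose and 2 fell when libraries were scaled to equal mRNA medians. They included DAL7 (3.80, SE 0.131), STN1 (3.48, SE 0.128) and TEN1 (3.27, SE 0.139), the last pair encoding telomere capping proteins. Against other mRNAs this list rose further (limma camera, adjusted p = 0.00586, and adjusted p = 0.703 with an estimated correlation). Of 137 ribosomal protein mRNAs 89 rose and none fell (86 and 0 adjusted over the list alone) with a median of 0.34, whereas under mRNA median scaling 2 rose and 133 fell, and they rose less than other mRNAs (adjusted p = 6.50e-35, and adjusted p = 0.339 with an estimated correlation). The 18 glycolysis and fermentation mRNAs had 5 that rose and 1 that fell, and under mRNA median scaling 1 rose and 16 fell (camera adjusted p = 2.93e-18, lower, and adjusted p = 0.193 with an estimated correlation). HXK1, a hexokinase gene, rose by 3.37 (SE 0.263) and GLK1 by 1.85 (SE 0.213), and the member that fell, named after its values were seen, was ADH1 (-0.41). Of 14 mating type and pheromone genes 8 rose and 1 fell (7 and 1 adjusted over the list alone), against 0 and 5 under mRNA median scaling (camera adjusted p = 7.03e-11, lower, and adjusted p = 0.0758 with an estimated correlation). STE6 rose by 1.87 (SE 0.143) and HO fell by 2.04 (SE 0.133), though whether the S288C pair carries the same HO allele is not given in the sources used here. HO rose in the xrn1 cells of W303, SK1 (1.79) and SK1_2n (2.38).

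Among heat shock chaperones 22 of 25 rose (HSP12 4.76, SE 0.199; SSA3 2.39, SE 0.129), with 3 higher and 13 lower under mRNA median scaling (camera adjusted p = 0.0114, lower than other mRNAs, and adjusted p = 0.793 with an estimated correlation). Of 4 alpha-cell genes 2 rose, and 1 rose and 1 fell under mRNA median scaling (adjusted p = 0.00586, lower, and adjusted p = 0.339 with an estimated correlation). Their median was 0.63 and their mean 1.24, the latter set by SAG1 (3.60, SE 0.283). In wild-type S288C, MF(ALPHA)1, MF(ALPHA)2 and STE3 lay near the floor (0.00286, 0.00396 and 0.0130). In xrn1 cells they were at 0.00736, 0.00936 and 0.0142. The lower call thus rests mostly on genes with little signal in either strain and does not show a response. Of 8 auxotrophic marker genes 5 rose, and none rose and 4 fell under mRNA median scaling (adjusted p = 0.0154, lower, and adjusted p = 0.483 with an estimated correlation). The markers LEU2 and URA3 had hardly any signal in wild type (0.00111 and 0.00498) or in xrn1 cells (0.00129 and 0.00361), so their values do not show a response. Under mRNA median scaling the camera calls of heat shock (adjusted p = 0.235), auxotrophic marker (0.359), mating type (0.274) and alpha-cell genes (0.550) ended.

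The other 9 lists were not separated from other mRNAs by camera on the deposited scale, while under mRNA median scaling histones (adjusted p = 0.0158) and oxidative phosphorylation (0.0240) were lower and meiosis genes higher (0.00658). All 10 histone mRNAs rose (median 0.91; all 10 fell under mRNA median scaling; adjusted p = 0.0618), among them HHF2 (1.12, SE 0.125) and HHF1 (0.96, SE 0.126). All 21 exosome and Nrd1 complex mRNAs rose (median 1.69; 2 higher and 9 lower under mRNA median scaling; adjusted p = 0.272), as did all 5 NMD factors (median 1.95; 2 and 0; adjusted p = 0.206), led by NMD4 (2.75, SE 0.132). For decapping and decay factors 24 of 25 rose and XRN1 fell (5 and 17 under mRNA median scaling; adjusted p = 0.381). Amino acid biosynthesis had 29 of 30 higher (5 and 19; adjusted p = 0.580), oxidative phosphorylation and the TCA cycle 35 of 36 (4 and 27; adjusted p = 0.974), and the phosphate regulon 16 of 17 (4 and 11; adjusted p = 0.367), counts in brackets being those under mRNA median scaling. General stress genes had 19 of 20 higher and 1 lower (10 and 4 under mRNA median scaling) and meiosis genes 22 of 23 higher (11 and 0). For these last lists the median exceeded that of all mRNAs while the test pointed lower (adjusted p = 0.561 and 0.827).

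On the deposited scale the median over all features moved by 1.68, and scaling to mRNA medians moved it to 0.02, with 1665 mRNAs higher and 2500 lower (39.98% of mRNA calls higher, against 99.7%). Under that scaling 1013 XUTs still lay higher and 156 lower.

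With the main pseudocount the W303 background gave the same class order as S288C. A pseudocount at the 25th percentile put the XUT median below the mRNA median in S288C (1.31 against 1.41) and in W303 (1.24 against 1.79). Of the XUTs 1680 rose and 35 fell (median 2.17), 794 SUTs rose (2.40), 648 CUTs rose (1.07), and 5622 mRNAs rose while 14 fell (1.97). XRN1 had 1 and 0 reads in the xrn1 libraries against 8465 and 4666 in wild type. HSP12, a membrane-protecting stress protein (6:107256-107585, plus strand), rose by 5.66 (SE 0.199), from 0.143 ± 0.0152 to 7.52 ± 0.643. TMA10 (12:783127-783387, minus strand) rose by 5.38 (SE 0.314) and RTS3 (7:808629-809420, minus strand) by 5.31 (SE 0.288). IMD2 (8:554396-555967, plus strand), an IMP dehydrogenase gene, fell by 1.21 (SE 0.140).

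CUT122 (6:106927-107215, plus strand), just upstream of HSP12 on the same strand, rose by 5.49 (SE 0.143) in W303. XUT0155 (4:382985-383284, plus strand), opposite PRM7, rose by 5.58 (SE 0.236) from 5 and 1 reads in the wild-type libraries. SUT262 (12:346168-346552, plus strand) rose by 5.28 (SE 0.202), SUT415 (16:565574-565814, plus strand), opposite HAL1, by 5.07 (SE 0.230) and SUT131 (7:778166-778614, plus strand) by 4.83 (SE 0.134). XUT0952 (2:35618-35972, minus strand) had 77 and 84 reads against 1 and 1 in wild type. SUT143 (7:1012276-1012484, plus strand) fell by 1.13 (SE 0.158).

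In W303 all 15 NMD targets rose (median 2.65; 11 higher and 1 lower under mRNA median scaling), above other mRNAs (adjusted p = 0.00663, and adjusted p = 0.861 with an estimated correlation). Ribosomal protein mRNAs rose in 129 of 137 cases (1 higher and 135 lower under mRNA median scaling), less than other mRNAs (adjusted p = 1.61e-31, and adjusted p = 0.371 with an estimated correlation). Glycolysis had 12 of 18 higher (11 adjusted over the list alone; 2 and 16 under mRNA median scaling; adjusted p = 3.26e-16, lower, and adjusted p = 0.189 with an estimated correlation). Mating type genes had 13 of 14 higher (0 and 4 under mRNA median scaling; adjusted p = 1.38e-05, lower, and adjusted p = 0.189 with an estimated correlation). Alpha-cell genes had 1 higher and 1 lower under either scaling (adjusted p = 6.00e-08, lower, and adjusted p = 0.0792 with an estimated correlation). In wild-type W303, MF(ALPHA)1, MF(ALPHA)2 and STE3 lay near the floor (0.00675, 0.00331 and 0.00985). In xrn1 W303 cells they were at 0.00554, 0 and 0.0250. This call thus rests mostly on genes with little signal in either strain and does not show a response to loss of Xrn1. Calls of mating type (adjusted p = 0.537) and alpha-cell genes (0.798) ended under mRNA median scaling. General stress genes (15 higher and 2 lower; camera adjusted p = 0.000428) and meiosis genes (10 and 1; 0.00273) gained a call under it. Among markers, HIS3 (4.50, SE 0.125), TRP1 (3.68, SE 0.122) and ADE2 (5.07, SE 0.168) rose, genes that often differ between laboratory strains. The median over all features was 1.94, and -0.05 under mRNA median scaling, which left 1750 mRNAs higher and 2485 lower (41.3% higher against 99.8%). Simulated data of this comparison gave 155 false calls among 9511 unchanged features, and 16 with voom. The 155 made up 48.0% of all calls in that simulation, which held 200 changed features. The adjusted p threshold was thus not held there, and W303 calls may include more false ones than it implies.

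In haploid SK1, XUTs (1514 rose, 46 fell; median 1.58) and SUTs (695 rose, 16 fell; 1.63) rose as well, while CUTs split, with 348 higher and 161 lower (median 0.17). Of the mRNAs 5350 rose and 62 fell (1.55), and XRN1 fell by 6.73 (SE 0.142). SPO24, a sporulation gene (16:645950-646153, plus strand), rose by 5.96 (SE 0.397), from 0.899 ± 0.488 to 52.0 ± 0.202. The repeated genes YLR159W (12:485345-485689, plus strand; 5.73, SE 1.83) and YLR161W (12:488997-489341, plus strand; 5.67, SE 1.86) rose, with reads that copies may share, and lost their calls without WT_SK1 replicate 2 (adjusted p = 0.0589 and 0.0563). The alpha-factor gene MF(ALPHA)2 (7:344791-345153, minus strand) fell by 2.14 (SE 0.262) and YGL188C-A (7:148824-148964, minus strand) by 1.49 (SE 0.377).

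The largest lncRNA rises in haploid SK1 were XUT1702 (15:578370-579747, minus strand; 4.78, SE 0.145), opposite BAG7, and SUT228 (11:143183-144319, plus strand; 4.65, SE 0.146). They were followed by XUT1436 (11:299754-300986, minus strand; 4.59, SE 0.207), opposite STB6, and SUT377 (15:701833-703401, plus strand; 4.59, SE 0.125). XUT0296 (5:427820-429766, plus strand), opposite PMD1, rose by 4.51 (SE 0.205) and SUT062 (4:957793-958601, plus strand), opposite YDR248C, by 4.50 (SE 0.208). The adjoining CUT542 (5:15605-15773, minus strand) and SUT503 (5:15773-15981, minus strand) fell by 3.06 (SE 0.228) and 2.67 (SE 0.190), and XUT0306 (5:565589-566027, plus strand) fell by 2.01 (SE 0.228).

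Ribosomal protein mRNAs in haploid SK1 went both ways, 59 higher and 19 lower (59 and 16 adjusted over the list alone; 2 and 134 under mRNA median scaling), below other mRNAs (adjusted p = 4.72e-60, and adjusted p = 0.205 with an estimated correlation). NMD targets rose in 15 of 15 cases (12 higher and 2 lower under mRNA median scaling), among them DAL7 (3.85, SE 0.131) and EST2 (3.43, SE 0.149), above other mRNAs (adjusted p = 0.00471, and adjusted p = 0.682 with an estimated correlation). Lower than other mRNAs were alpha-cell genes (1 rose and 1 fell, 0 and 1 adjusted over the list alone; adjusted p = 1.13e-07, and adjusted p = 0.0832 with an estimated correlation) and glycolysis (9 rose, 1 fell; adjusted p = 1.13e-07). So were histones (9 rose, 1 fell; adjusted p = 0.00538) and meiosis genes (18 of 23 rose, 17 adjusted over the list alone; adjusted p = 0.0113), and for these and for glycolysis adjusted p = 0.682 with an estimated correlation. Under mRNA median scaling the higher and lower counts of these 4 lists became 0 and 3, 2 and 16, 0 and 9, and 6 and 6, and the calls of alpha-cell genes (adjusted p = 0.276) and meiosis genes (0.381) ended. General stress genes (16 higher and 1 lower; camera adjusted p = 0.00106) and oxidative phosphorylation (2 and 26; 0.00131) gained a call under it. The median over all features was 1.43, and -0.13 under mRNA median scaling, with 1859 mRNAs higher and 2473 lower (42.9% higher against 98.9%).

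On the deposited scale diploid SK1 showed the largest mRNA shift, with 5597 rising, 23 falling and a median of 3.14. XUTs (1655 rose, 26 fell; median 2.09), SUTs (746 rose; 2.35) and CUTs (545 rose, 50 fell; 0.79) rose less than mRNAs on this scale. The size of this gap depends on the pseudocount of 0.00576637, as wild-type median XUT densities were only 0.00696 and 0.00829. The XUT median was 2.79 with a pseudocount of 0.000576637. It was 0.94 with one at the 25th percentile (mRNAs 2.72) and 2.86 with voom (mRNAs 3.29). The wild types differed too: 5428 mRNAs were lower in WT_SK1_2n than in WT_SK1 and 43 higher (median -1.41), and the diploid wild type had the largest snoRNA share of reads, 18.5% and 16.6%. XRN1 fell by 5.51 (SE 0.142). RCK1 (7:207033-208571, plus strand), a kinase gene of the oxidative stress response, rose by 6.49 (SE 0.257), DCI1 (15:674352-675167, minus strand) by 6.14 (SE 0.149) and DAL7 (9:413015-414679, minus strand) by 5.93 (SE 0.131).

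The flocculin gene FLO11 (9:389572-393675, minus strand) fell by 1.64 (SE 0.198) and the alpha-agglutinin gene SAG1 (10:442909-444861, minus strand) by 1.07 (SE 0.283) in the diploid. SUT812 (16:347673-348290, minus strand; 5.68, SE 0.148) and the overlapping XUT1758 (16:347547-348311, minus strand; 5.62, SE 0.145) led the lncRNAs with SUT638 (10:454763-454939, minus strand; 5.64, SE 0.274). SUT509 (5:186934-188070, minus strand) rose by 5.49 (SE 0.159), SUT103 (6:89579-90771, plus strand), opposite EPL1, by 5.46 (SE 0.129) and SUT497 (4:1507402-1507498, minus strand) by 5.45 (SE 0.421), the last from 1 and 5 wild-type reads. CUT542 (fell by 3.20, SE 0.228), SUT503 (fell by 3.12, SE 0.190) and XUT1215 (7:323221-323654, minus strand; fell by 1.26, SE 0.272) were lower.

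All 4 alpha-cell genes fell in diploid xrn1 cells, under either scaling, against a rise of other mRNAs (adjusted p = 2.95e-36, and adjusted p = 8.48e-05 with an estimated correlation). They were MF(ALPHA)2 (-3.89, SE 0.262), STE3 (-2.30, SE 0.573), MF(ALPHA)1 (-1.68, SE 0.646) and SAG1. The wild-type replicates stood apart for these genes, replicate 2 exceeding replicate 1 by 1.76 for STE3 and 1.91 for MF(ALPHA)1, and by a median of 1.48 for GPA1, STE4, STE18, FUS3 and FAR1, which haploid cells express. Mating type and pheromone genes had 9 of 14 higher and 1 lower (8 and 1 adjusted over the list alone; 2 and 8 under mRNA median scaling), below other mRNAs (adjusted p = 4.87e-13, and adjusted p = 0.0189 with an estimated correlation). STE2 rose by 4.93 (SE 0.190), STE6 by 3.72 (SE 0.143), and STE18, named after its values were seen, fell by 1.85. No other list call of the 6 comparisons held with an estimated correlation, and that of the mating type genes ended under mRNA median scaling (adjusted p = 0.332).

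Ribosomal proteins (135 higher, 1 lower; 2 and 135 under mRNA median scaling), glycolysis (17 higher; 1 and 17) and meiosis genes (22 higher; 7 and 9) rose less than other diploid mRNAs, with adjusted p = 3.17e-12, 1.94e-09 and 5.01e-05. With an estimated correlation these were adjusted p = 0.809, 0.394 and 0.305. Exosome genes (21 of 21 higher; 10 and 5 under mRNA median scaling) and NMD targets (15 of 15; 14 and 0) rose more, with adjusted p = 0.0443 and 0.0153, and adjusted p = 0.892 and 0.809 with an estimated correlation. Meiosis genes (adjusted p = 0.331) and exosome genes (0.0978) were no longer called under mRNA median scaling. Calls were gained under it by NMD factors (4 higher and 0 lower; camera adjusted p = 0.0443), amino acid biosynthesis (2 and 28; 1.29e-05) and oxidative phosphorylation (1 and 32; 2.39e-05). The median over all features was 2.68, and -0.39 under mRNA median scaling, where 1806 mRNAs and 387 XUTs were higher against 2775 and 880 lower (39.4% of mRNA calls higher against 99.6%).

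Across the 4 xrn1 comparisons 1389 of 1798 XUTs (77.3%) and 673 of 839 SUTs (80.2%) rose in every background, against 316 of 923 CUTs (34.2%). The effect of the deletion differed from that in S288C for 2913 features in W303 (2144 with a larger and 769 with a smaller change) and for 4031 in SK1 (1116 and 2915). Of 546 chromosome 11 features, which carry the S288C offset, 262 had a smaller change in W303 and 424 in SK1, and 8 and 12 a larger one. Of 9166 features elsewhere 507 and 2491 had a smaller change, and 2136 and 1104 a larger one. CUTs made up 570 of the smaller effects in SK1, with a median difference of -1.12. Diploid and haploid SK1 differed at 7270 features, 6991 of them with a larger change in the diploid, and at 5179 under mRNA median scaling. These directions are those of the deposited scale. With mRNA medians made equal, the median over all features was 0.02 in S288C, -0.05 in W303, -0.13 in SK1 and -0.39 in SK1_2n, so whether W303 changed more than S288C, and the diploid more than the haploid, depends on the scale.

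CUT705 (11:157723-158298, minus strand) and the overlapping XUT1424 (11:157686-158319, minus strand), opposite the aminopeptidase gene APE2, rose by 3.46 and 3.45 in S288C. Their W303 values were -0.80 and -0.79, differences of -4.26 (SE 0.314) and -4.24 (SE 0.313), and in SK1 the differences were -3.95 and -3.92. XUT0605 (11:578511-578888, plus strand) differed by -3.45 (SE 0.324) in W303. ADE2 (15:564476-566191, minus strand), an adenine biosynthesis gene, rose by 5.07 in W303 and 1.41 in S288C, and XUT0155 by 5.58 and 2.08. For XUT0155 the difference of 3.50 was 2.31 and lost its call with a pseudocount of 0.000576637.

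XUT0790 (15:18276-18704, plus strand) rose by 4.95 in S288C with a value of 0.51 in SK1, a difference of -4.44 (SE 0.338), and XUT0911 differed by -3.75 (SE 0.290). SAG1 rose by 3.60 in S288C against -0.17 in SK1. CTR3 (12:947253-947978, plus strand), a copper transporter gene, rose by 3.67 in diploid SK1 with -0.41 in the haploid, a difference of 4.08 (SE 0.232), whereas SNZ1 rose by 3.18 in the haploid and fell by 0.76 in the diploid. SUT836 (16:781971-785379, minus strand), opposite AXL1, rose by 5.38 and 1.71, and the overlapping XUT1794 (16:781936-785600, minus strand) by 5.26 and 1.67. AFB1 (12:228908-229582, minus strand), which encodes the a-factor barrier of alpha cells, fell by 3.05 in the diploid, with a value of 0.58 in the haploid. The W303 count rested most on single libraries, falling to 1359 without xrn1_W303 replicate 2, 1407 and 1556 without xrn1_S288C replicates 2 and 1, and 1547 and 1815 without WT_S288C replicates 1 and 2. It rose to 4903 when libraries were scaled by the mean log2 of snoRNAs and to 5127 in models of the compared groups alone.

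In dcp2-7 cells at 37 °C, XUTs (1326 rose, 72 fell; median 1.07), SUTs (674 rose, 19 fell; 1.30) and CUTs (381 rose, 106 fell; 0.31) rose more often than they fell. Of the mRNAs 4621 rose and 89 fell (median 0.71), and of the tRNAs 15 rose and 103 fell. DCP2 signal (14:402652-405564, minus strand) rose by 0.68 (SE 0.127), with -0.18 under mRNA median scaling, and since dcp2-7 is a point-mutant allele this level does not check the label. Other genes separated the strains: LYS2 had 2 and 4 reads in dcp2-7 against 13172 and 15209 in wild type, and URA3 was at 0.530 ± 0.0212 against 0.00311 ± 0.00196. HO fell by 2.07 (SE 0.133), with the same limit as in xrn1 S288C. As the strains differ at genes other than DCP2, strain differences and effects of dcp2-7 cannot be told apart in the RNA-seq and Terminator comparisons.

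The largest rises were RTC3 (8:280820-281155, plus strand; 3.97, SE 0.216), from 0.312 ± 0.00822 to 4.98 ± 0.323, and YER053C-A (5:260933-261046, minus strand; 3.81, SE 0.279). HSP12 rose by 3.42 (SE 0.199), YGR174W-A (7:846655-846741, plus strand) by 3.39 (SE 0.278) and MOH1 (2:126828-127244, plus strand) by 3.30 (SE 0.169). MBF1 (15:877230-877685, minus strand), a transcriptional coactivator gene, rose by 3.30 (SE 0.220). ALD6, the cytosolic acetaldehyde dehydrogenase gene (16:432588-434090, plus strand), fell by 2.18 (SE 0.133), from 6.93 ± 1.30 to 1.51 ± 0.0616. HUG1 (13:158760-158966, plus strand) fell by 1.45 (SE 0.191), GRE2 (15:43694-44722, plus strand) by 1.31 (SE 0.185) and the iron-uptake mannoprotein gene FIT2 (15:1059531-1059992, plus strand) by 1.26 (SE 0.342). YOL013W-A (15:301047-301238, plus strand) fell by 1.15 (SE 0.136) and the malate dehydrogenase gene MDH2 (15:81787-82920, minus strand) by 1.09 (SE 0.149).

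XUT1395 (10:598737-599614, minus strand), opposite the bud-site gene BUD4, rose by 3.87 (SE 0.192) in dcp2-7. SUT158 (8:221423-222335, plus strand) and the overlapping XUT0439 (8:221468-222859, plus strand), both opposite GIC1, rose by 3.81 (SE 0.210) and 3.73 (SE 0.197). XUT0678 (12:1010949-1011369, plus strand), opposite ECM30, rose by 3.80 (SE 0.184), SUT664 (11:259611-260027, minus strand) by 3.76 (SE 0.273) and SUT097 (5:489926-491262, plus strand), opposite YER158C, by 3.71 (SE 0.164). XUT0463 (8:549517-549756, plus strand) fell by 1.96 (SE 0.212), CUT294 (13:348594-348810, plus strand), opposite SUB1, by 1.44 (SE 0.221) and XUT1419 (11:95999-96271, minus strand), opposite ASH1, by 1.29 (SE 0.176).

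Histones stood apart in dcp2-7: 5 of 10 fell and none rose, and all 10 fell under mRNA median scaling, below other mRNAs (adjusted p = 8.43e-18, and adjusted p = 0.0851 with an estimated correlation). HTA2 fell by 1.09 (SE 0.119), HHF1 by 1.04 (SE 0.126) and HHT1 by 0.92 (SE 0.141). Heat shock chaperones rose in 24 of 25 cases (11 higher and 4 lower under mRNA median scaling), among them HSP26 (2.77, SE 0.236) and SSA3 (2.00, SE 0.129), above other mRNAs (adjusted p = 0.0430, and adjusted p = 0.842 with an estimated correlation). All 15 NMD targets rose (9 and 0 under mRNA median scaling), including EST3 (2.13, SE 0.160) and TEN1 (2.08, SE 0.139), and all 5 NMD factors rose (3 and 0), led by NMD4 (2.28, SE 0.132). Both lists lay above other mRNAs (adjusted p = 0.00737 and 0.0430), with adjusted p = 0.672 for each with an estimated correlation. Ribosomal proteins rose in 74 of 137 cases (64 adjusted over the list alone; 4 and 129 under mRNA median scaling), below other mRNAs (adjusted p = 4.15e-07, and adjusted p = 0.842 with an estimated correlation). Of the alpha-cell genes SAG1 rose (1 and 2 under mRNA median scaling; adjusted p = 0.0430, lower), while MF(ALPHA)1 and MF(ALPHA)2 lay near the floor in wild type (0.00375 and 0.00729). Mating type genes had 8 higher and 1 lower (7 and 1 adjusted over the list alone; 1 and 2 under mRNA median scaling), with a median above and a mean below that of all mRNAs (adjusted p = 0.0254, lower). For these lists adjusted p = 0.672 with an estimated correlation and 0.814 under mRNA median scaling. Calls were gained under that scaling by general stress genes (10 higher and 4 lower; camera adjusted p = 0.00679), glycolysis (3 and 12; 0.0354) and the phosphate regulon (6 and 3; 0.0354).

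The amino acid list of dcp2-7 cells had 22 higher and 3 lower of 30 (4 and 14 under mRNA median scaling; camera adjusted p = 0.109). The lower ones were LYS2, which separated the strains above, ARG1 (-0.70) and HOM2 (-0.30), the last pair named after their values were seen. Scaling to mRNA medians moved the median of all features from 0.73 to -0.06 and left 1348 mRNAs higher and 2292 lower (37.0% higher against 98.1%). The count of mRNAs that fell was 134 without WT_37C replicate 1, 51 without WT_37C replicate 2 and 52 without dcp2_37C replicate 2.

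Cells lacking Upf1 had 1478 XUTs higher and 2 lower (median 1.27), 710 SUTs higher (1.41) and 356 CUTs higher (0.35). The XUT median was 0.61 with a pseudocount at the 25th percentile, 1.67 with one of 0.000576637 and 1.71 with voom. Of the mRNAs 2710 rose and 30 fell, with a median of 0.32. NAM7 (13:426712-429627, minus strand) fell by 6.41 (SE 0.135), from 0.585 ± 0.00555 to 0.00119 ± 0.000453. PET18 (3:154012-154659, minus strand) rose by 3.98 (SE 0.131) and DAL7, the malate synthase paralog of allantoin degradation, by 3.94 (SE 0.131), from 0.0537 ± 0.00135 to 0.906 ± 0.0652. YOL163W (15:9597-10106, plus strand) rose by 3.90 (SE 0.182), YNR068C (14:760067-760885, minus strand) by 3.62 (SE 0.125), HTL1 (3:155320-155556, plus strand) by 3.57 (SE 0.122) and YCR095W-A (3:289639-289797, plus strand) by 3.57 (SE 0.155). PHO89, a sodium-phosphate cotransporter gene (2:796798-798522, minus strand), fell by 1.74 (SE 0.253) and the cell wall gene CWP1 (11:261132-261851, plus strand) by 1.55 (SE 0.260).

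Among lncRNAs, XUT0788 (15:3524-3979, plus strand) rose by 3.52 (SE 0.223) in upf1 cells and XUT1467 (11:661427-662438, minus strand), opposite GEX2, by 3.48 (SE 0.173). CUT185 (9:32601-32721, plus strand) rose by 3.48 (SE 0.313) and SUT745 (14:204918-206742, minus strand), opposite YTP1, by 3.40 (SE 0.138). SUT777 (15:447260-448364, minus strand) and the overlapping XUT1693 (15:447124-448428, minus strand), both opposite the cytochrome c1 gene CYT1, rose by 3.44 (SE 0.180) and 3.41 (SE 0.186).

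Reported NMD targets rose in 14 of 15 cases in upf1 cells (14 adjusted over the list alone; 13 higher and 2 lower under mRNA median scaling), with a median of 1.54. Besides DAL7 they were led by STN1 (3.10, SE 0.128), TEN1 (2.43, SE 0.139) and EST2 (2.56, SE 0.149), whereas UBP7 was at 0.19. The list rose more than other mRNAs (adjusted p = 2.29e-08, and adjusted p = 0.427 with an estimated correlation). Meiosis genes rose in 16 of 23 cases (17 adjusted over the list alone; 12 and 0 under mRNA median scaling), among them IME2 (2.60, SE 0.153), the kinase of meiotic entry, ZIP1 (2.57, SE 0.147) and REC104 (2.50, SE 0.139), above other mRNAs (adjusted p = 0.00262, and adjusted p = 0.575 with an estimated correlation). NMD4 (2.63, SE 0.132), EBS1 (1.71, SE 0.157) and NMD2 (0.69, SE 0.140) rose while NAM7 fell. The phosphate regulon had 2 higher and 5 lower of 17 (1 and 4 adjusted over the list alone; 1 and 14 under mRNA median scaling), below other mRNAs (adjusted p = 1.74e-06, and adjusted p = 0.427 with an estimated correlation). In it GIT1, a glycerophosphoinositol transporter gene, rose by 2.94 (SE 0.160), and PHM6 fell by 0.65 (SE 0.168).

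Lower than other mRNAs in upf1 cells were glycolysis (HXK1, -1.04, SE 0.263, and GLK1, -0.73, SE 0.213, fell; 0 and 18 under mRNA median scaling; adjusted p = 1.89e-05) and oxidative phosphorylation (6 rose, 4 adjusted over the list alone; 0 and 33; adjusted p = 1.89e-05). So were ribosomal proteins (27 rose, 15 adjusted over the list alone; 4 and 127; adjusted p = 0.000540), general stress genes (5 rose and 2 fell; 3 and 13; adjusted p = 0.000543), mating type genes (1 rose, 0 adjusted over the list alone; 0 and 5; adjusted p = 0.000540) and histones (0 called; 0 and 8; adjusted p = 0.00568). With an estimated correlation these 6 had adjusted p = 0.668, 0.685, 0.897, 0.685, 0.427 and 0.685. The calls of general stress genes (adjusted p = 0.497), mating type genes (0.554) and histones (0.0985) ended under mRNA median scaling. Decapping and decay factors (0 higher and 20 lower; camera adjusted p = 0.0120) gained a call under it. HSP12 fell while ALD3 (1.34, SE 0.162) and CTT1 (1.38, SE 0.291) rose.

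The upf1 scale is uncertain, because WT_UPF1 and WT_S288C are the same strain and yet 4020 mRNAs were lower and 74 higher in the former (median -0.55). Scaling to mRNA medians moved the median of all features from 0.46 to -0.09 and left 1305 mRNAs higher and 3036 lower (30.1% higher against 98.9%), but 1167 XUTs higher and 83 lower. The count of mRNAs that fell was 18 without WT_UPF1 replicate 2 and 17 without upf1 replicate 2.

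To ask whether the same lncRNAs respond to Upf1 and Xrn1, whose effects have separate wild types, calls were compared. XUTs that rose in both numbered 1434, against 1412.24 expected from independent lists (Fisher's exact test, two-sided, across features, p = 7.04e-09), and lncRNAs 2491 against 2373.21 (p = 1.58e-60). Under mRNA median scaling 838 XUTs rose in both. Since XUTs were defined by sensitivity to Xrn1 and 1718 of 1798 rose in xrn1 cells, any XUT overlap with xrn1 was nearly fixed in advance. The Fisher tests here also treat features as independent, although 1655 lncRNAs share reads with another, and signal level was not matched. Their p-values thus do not show that Upf1 and Xrn1 act on the same lncRNAs. On the deposited scale the upf1 change was smaller than the xrn1 S288C change at 1101 XUTs and larger at 101 (median difference -0.86), but under mRNA median scaling the XUT median was 0.90 in upf1 and 0.64 in xrn1 S288C, so the direction depends on the scale. For dcp2-7 and xrn1 the XUTs that rose in both numbered 1314 against 1267 expected (Fisher's exact test, p = 1.86e-29), and on the deposited scale the dcp2-7 change was smaller at 1269 and larger at 37 (XUT medians of 0.38 and 0.64 under mRNA median scaling). The chromosome 11 offset of xrn1 S288C enters these counts. Over all classes 508 of 546 chromosome 11 features had a smaller change in upf1 and 511 in dcp2-7, against 6364 and 6098 of 9166 elsewhere.

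The series title names double-stranded RNA as a block to NMD, so lncRNAs lying opposite an mRNA were compared with the others in upf1 cells. The 2148 with an mRNA on the other strand had a median change of 1.15 and the 1412 without one 0.94, a difference of 0.21 that camera did not separate (p = 0.283, and p = 0.784 with an estimated correlation). The shares that rose were 71.4% and 71.6%. With an overlap of at least 200 nt the difference was 0.33 (p = 0.0165, and p = 0.564 with an estimated correlation). With only mRNAs above the mRNA median counted as opposite it was -0.09 (p = 0.215, and p = 0.730 with an estimated correlation), and CUTs gave -0.18 (p = 0.0157, and p = 0.289 with an estimated correlation). Under the stricter filter the 1 nt difference was 0.46 (p = 0.00453 with the preset correlation). By class at 1 nt of overlap it was 0.26 for XUTs (p = 0.0507), 0.40 for SUTs (p = 0.00383, and p = 0.520 with an estimated correlation) and -0.14 for CUTs (p = 0.178). At 200 nt, XUTs gave 0.31 (p = 0.0124, and p = 0.533 with an estimated correlation) and SUTs 0.59 (p = 6.53e-07, and p = 0.314 with an estimated correlation). The upf1 minus xrn1 difference between both groups was 0.07 (camera with the preset correlation, p = 0.913), and the split gave 0.03 in xrn1 S288C (p = 0.233) and -0.15 in dcp2-7 (p = 0.564). At 200 nt the split also passed in xrn1 S288C, with 0.11 for lncRNAs (p = 0.0287, and p = 0.598 with an estimated correlation). For SUTs at 200 nt it gave 0.65 in SK1 and 0.84 in SK1_2n (p = 3.85e-08 and 2.64e-07, and p = 0.268 and 0.298 with an estimated correlation), so it is not particular to upf1. XUTs opposite an mRNA are longer, with a median of 709.5 nt against 449.5 nt. These camera p-values are not adjusted over the splits shown, and annotated overlap does not measure a duplex in cells.

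Terminator treatment asks which accumulated RNAs carry a 5'-monophosphate, that is, have lost their cap. The treated wild-type and xrn1 columns name no background and were assigned to S288C from the sample titles. The response compares Terminator libraries with rRNA-depleted ones, 2 preparations of RNA, on the snoRNA scale. Wild-type S288C signal moved both ways between them, as for MFA1 (3.50 rRNA-depleted, 20.7 Terminator) and XRN1 (1.60 and 0.911). A response within one strain thus does not measure the enzyme alone. It was much lower in xrn1 than in wild-type S288C cells: lower at 2744 of 3516 lncRNAs and higher at 2 (median -1.19), and lower at 5019 of 5715 mRNAs and higher at 10 (median -1.03). By class the medians were -1.40 for SUTs, -1.25 for XUTs, -0.85 for CUTs and -0.16 for snoRNAs. SUT324 (14:200226-200410, plus strand) gave -2.84 (SE 0.353), with a response of -2.04 in xrn1 and 0.81 in wild type, and SUT131 gave -2.83 (SE 0.384; -2.59 and 0.24). CUT425 (16:608542-608646, plus strand) gave -2.79 (SE 0.550), CUT543 (5:51773-51973, minus strand) -2.73 (SE 0.588) and XUT1526 (12:1029981-1030616, minus strand) -2.68 (SE 0.214). The mRNAs with the lowest response were RTS3 (-2.70, SE 0.232), the autophagy gene ATG41 (16:74309-74719, minus strand; -2.61, SE 0.223) and YKL068W-A (11:309206-309442, plus strand; -2.59, SE 0.216). Camera did not separate lncRNAs from other features (p = 0.220, and p = 0.789 with an estimated correlation), its direction being higher although their median was lower. Under mRNA median scaling 678 lncRNAs had a lower response.

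**Figure D3:**
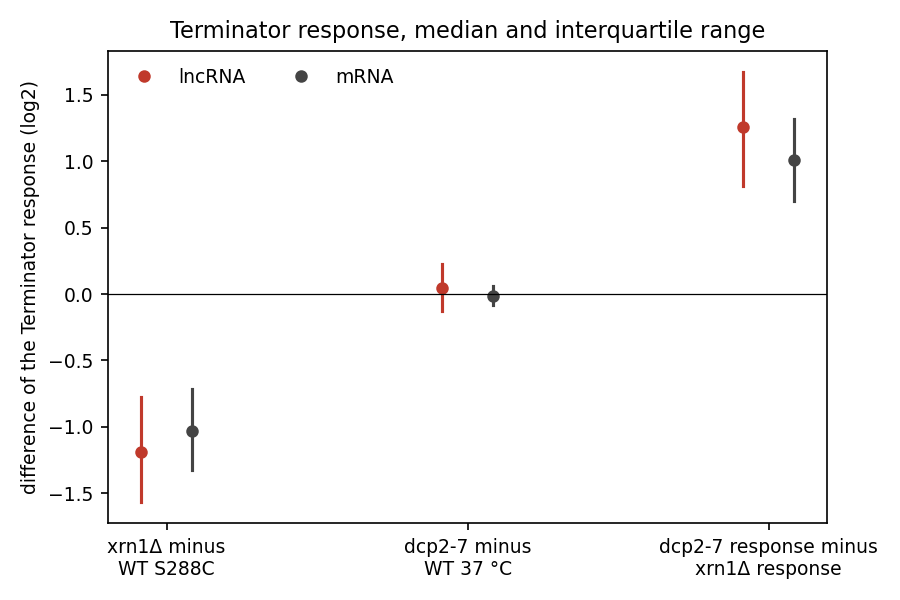
Difference between mutant and wild type in the log2 response to Terminator, by feature class, for xrn1 S288C and dcp2-7. The median lncRNA difference was -1.19 in xrn1 cells and 0.04 in dcp2-7 cells.

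In dcp2-7 cells the Terminator response hardly differed from wild type, with 2 lncRNAs lower and 1 higher (median 0.04) and 1 mRNA each way (median -0.01) by limma. At an unadjusted p under 0.05, 71 lncRNAs were lower and 107 higher. With voom 1 was lower, and with replicates paired by number 11 were. The lncRNA that the naming rule gave, CUT719 (11:386637-386949, minus strand), opposite TFA1, had a response lower by -1.38 (SE 0.272, adjusted p = 0.0242), a call lost with voom (adjusted p = 0.0729), under mRNA median scaling (adjusted p = 0.137) and on leaving out any of 6 of the 8 libraries (adjusted p = 0.0762 to 0.305), and kept under the other settings. FIT3 (15:1060441-1061055, minus strand), an iron-uptake mannoprotein gene, gave -2.01 (SE 0.270), a call lost without WT_37C replicate 1 (adjusted p = 0.0546). As a class lncRNAs lay higher than other features (camera p = 0.0128, and p = 0.590 with an estimated correlation). Between the mutants, the response was higher in dcp2-7 at 2316 lncRNAs and lower at 10 (median 1.26), and higher at 4253 mRNAs (median 1.01). Under mRNA median scaling the lncRNA median was 0.28, and camera then separated lncRNAs (p = 3.52e-08 with the preset correlation).

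CAGE asks whether decapping-deficient cells carry capped 5' ends that wild type lacks. The wild-type list held 9340 positions and the dcp2-7 list 10183, of which 2666 (26.2%, 95% Wilson interval 25.3 to 27.0) had no identical wild-type position and 1690 (16.6%) none within 50 nt. Of wild-type positions 1823 (19.5%) had no identical dcp2-7 position. Each list pools its replicates and gives no height or depth, so no replicate test was possible and intervals cover counting error alone. The 1690 dcp2-7 positions were assigned to lncRNAs in 545 cases (32.2%), against 945 of 8493 (11.1%) of the others, and upstream of mRNAs in 274 (16.2%) against 5955 (70.1%). Positions upstream of or inside an mRNA on their strand were assigned to it first. The rest went to a lncRNA if inside it or within 50 nt of it. The 931 wild-type positions without a dcp2-7 one within 50 nt were assigned to lncRNAs in 202 cases (21.7%) and upstream of mRNAs in 289 (31.0%), so part of this contrast is shared by unmatched positions of either list.

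A wild-type position lay within 50 nt of the 5' end of 878 of 3570 lncRNAs (24.6%, interval 23.2 to 26.0) and a dcp2-7 position at 1092 (30.6%, 29.1 to 32.1). At 351 lncRNAs there was a position in dcp2-7 alone and at 137 in wild type alone (exact McNemar test across features, two-sided, p = 1.07e-22). XUTs accounted for much of this, with 470 (26.1%) in wild type and 658 (36.6%) in dcp2-7 (exact McNemar test, p = 1.42e-29), whereas CUTs numbered 123 and 114 (p = 0.362) and SUTs 285 and 320 (p = 0.00141). The same window on the other strand gave 93 and 95 lncRNAs (2.61% and 2.66%), which measures background. The McNemar tests treat lncRNAs as independent, although 1655 overlap another on their strand. A position can then count for both, as 221468 does for SUT158 and XUT0439. Their p-values also cover no spread between replicates, which the lists pool. The 351 lncRNAs had a median RNA-seq change in dcp2-7 of 1.51, with 316 rising (90.0%), against 1.32 for the 741 with a position in both lists (619 rising) and 0.71 for the 2331 with a position in neither.

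The lncRNAs with a dcp2-7 position and no wild-type position were led by SUT158, whose position 221468 lies 45 nt into it and is the 5' end of XUT0439. SUT664 had a position at 260008, 19 nt from its 5' end. XUT1229 (7:454834-455298, minus strand), opposite the kinase gene ALK1, rose by 3.70 (SE 0.228) with a position exactly at its 5' end, 455298. XUT0816 (15:435888-436647, plus strand), opposite the microtubule bundling gene ASE1, rose by 3.68 (SE 0.182) with a position at 435888.

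**Figure D4:**
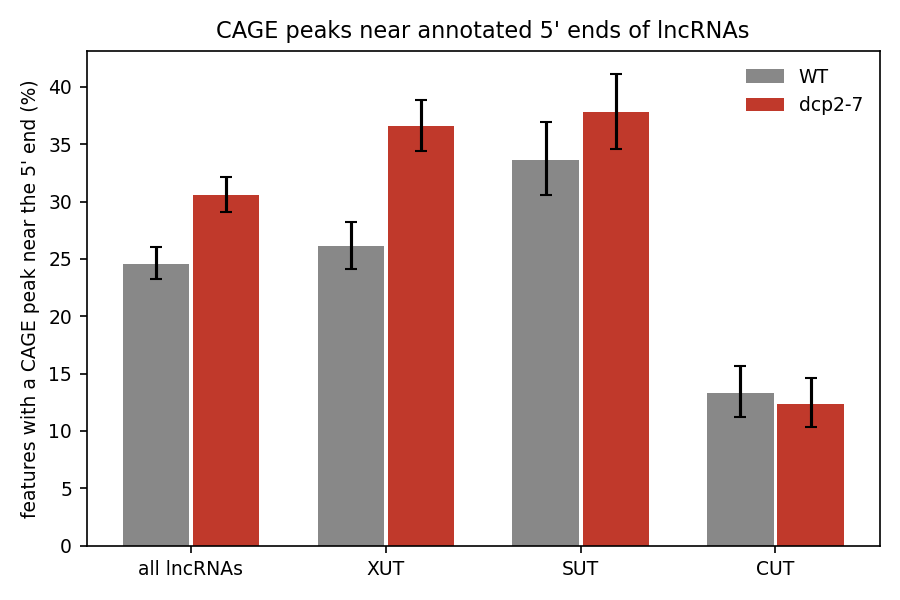
Share of annotated lncRNA 5' ends with a CAGE position within 50 nt on the same strand, by class, in wild type and dcp2-7, with 95% Wilson intervals. The share of XUTs was 26.1% in wild type and 36.6% in dcp2-7.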

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

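Of the tests below, the differences between strains and between mutants and the extra-copy test for chromosome 11 were set out beforehand, and the tests of the other explanations were chosen only after the result was seen. The differences between strains and between mutants come from interaction tests, while the mRNA rise and the fall of alpha-cell genes come from comparisons of mutant and wild type. The effect of losing Xrn1 differed between W303 and S288C at 2913 features, between SK1 and S288C at 4031, and between diploid and haploid SK1 at 7270.

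In W303 against S288C the largest differences were CUT705 (-4.26), XUT1424 (-4.24), ADE2 (3.66), XUT0155 (3.50) and XUT0605 (-3.45). In SK1 against S288C they were XUT0790 (-4.44), CUT705 (-3.95), XUT1424 (-3.92), SAG1 (-3.77) and XUT0911 (-3.75), with strain and mating type not separable for SAG1. In diploid against haploid SK1 they were CTR3 (4.08), SNZ1 (-3.93), SUT836 (3.67), AFB1 (-3.63) and XUT1794 (3.59). The Terminator response of lncRNAs differed between dcp2-7 and xrn1 S288C at 2326 of them.

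CUT705, XUT1424 and XUT0605 lie on chromosome 11, whose mRNAs rose more than others in xrn1 S288C cells. A hypothesis is an extra copy of this chromosome in those cells, and the lowest median over 10 consecutive parts of the chromosome, of 31 or 32 mRNAs each, and both libraries was 0.793, so the offset spans it from end to end, as an extra copy needs. A response of its genes to loss of Xrn1 in every background is excluded by W303 and SK1, where the chromosome differed from the rest by -0.0113 at the largest in size. Other strains cannot exclude a response limited to S288C. Low signal in the S288C wild type is excluded by the other wild types (-0.0188). DNA was not measured, and the offset explains only part of differences as large as that of CUT705.

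The rise of mRNAs as a class depends on the snoRNA scale. In haploid xrn1 cells the 9 other stable RNAs (snRNAs, SCR1, RPR1 and TLC1) had medians of at most 0.245 and tRNAs of at most 0.30. Single members went both ways, such as RPR1 (0.516 in W303) and TLC1 (-0.788 in SK1). These values argue against a loss of snoRNA reads alone. A loss that snoRNAs shared with the other stable RNAs would also leave such medians near the snoRNA scale, so it cannot be excluded. In the diploid the stable RNAs had a median of 0.10 but tRNAs rose by 1.49, so loss of snoRNA reads and a rise of mRNAs cannot be told apart there. A scale difference as large as that between WT_UPF1 and WT_S288C would not account for the xrn1 rise, as the lowest xrn1 mRNA median exceeds it by 1.00. Other wild-type pairs were not used for this test, so a larger scale difference is not excluded. For upf1 the mRNA median falls short of the difference between WT_UPF1 and WT_S288C by -0.221. A rise of mRNAs and a scale difference thus cannot be told apart in upf1 cells.

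All alpha-cell genes fell in diploid xrn1 cells while other mRNAs rose. A hypothesis is that the wild-type diploid cultures held some alpha-type haploid cells: genes of haploid cells were higher by 1.48 in replicate 2 than in replicate 1 of that wild type, against 0.25 for all mRNAs, though MF(ALPHA)2 differed by -0.16. The mutant cultures differed too, with MF(ALPHA)1 at 0.847 and 0.159 and FAR1 at 0.271 and 0.0602 in replicates 1 and 2, and mutant replicate 1 exceeds wild-type replicate 1 for MF(ALPHA)1 (0.618). The median effect was lower in the diploid than in the haploid by -2.21, but MF(ALPHA)2 fell in both. A response of these genes to loss of Xrn1 and a mixture of cells cannot be told apart.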

How the results depend on the processing

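Scaling libraries to equal mRNA medians changed most. Called higher were 1736 lncRNAs in xrn1 S288C, 1394 in W303, 1090 in SK1, 688 in SK1_2n and 1399 in dcp2-7. Higher mRNAs were 1665, 1750, 1859 and 1806 in the xrn1 comparisons, 1348 in dcp2-7 and 1305 in upf1, and lower ones 2500, 2485, 2473, 2775, 2292 and 3036. The Terminator response was lower at 678 lncRNAs in xrn1 and 1 in dcp2-7, XUTs that rose in both upf1 and xrn1 numbered 838, and the dcp2-7 minus xrn1 Terminator median was 0.28 with a camera p of 3.52e-08, now past its threshold. Reversed were DCP2 (-0.18), the mRNA medians (-0.12, -0.11, -0.0986 and -0.20 in xrn1, -0.115 in dcp2-7, -0.27 in upf1) and the SK1_2n XUT median (-0.445). For 6 lists the camera direction turned while the call ended. The median relative to all mRNAs changed sign for meiosis genes in SK1 (0.0142) and SK1_2n (0.0818), and kept its sign for alpha-cell genes in S288C (-0.0800), W303 (-0.59) and dcp2-7 (-0.16) and for mating type genes in dcp2-7 (0.194). The scale moves these by construction, and the tests of the snoRNA scale are those given above for xrn1 and upf1.

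Fewer features or a fold minimum lower the next counts by construction, but not the antisense difference or the rise from 2 to 6 lncRNAs in the dcp2-7 Terminator test, whose causes were not tested. The stricter filter left 1542, 1489, 1288, 1473, 1257 and 1281 lncRNAs higher (S288C, W303, SK1, SK1_2n, dcp2-7, upf1), 7 mRNAs lower in W303 and 11 in SK1_2n, 1474 and 6 lncRNAs with a lower Terminator response in xrn1 and dcp2-7, 566 XUTs higher in both upf1 and xrn1, and an antisense difference of 0.46 (camera p = 0.00453 with the preset correlation, the only one run at this filter). Leaving out lncRNAs that overlap another on their strand, chosen after seeing the data, left 1694, 1592, 1322, 1533, 1124 and 1242 lncRNAs higher, 1282 and 0 with a lower Terminator response, and 830 XUTs in both. With a 2-fold minimum, mRNAs lower were 5, 7, 11, 15, 24 and 7, mRNAs higher 1606 in dcp2-7 and 1003 in upf1, and strain differences 840 (W303) and 2245 (SK1).

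Other settings moved class medians, small counts and the number of W303 differences (2913), and the cause was not tested. The 25th-percentile pseudocount moved 10 class medians and kept 2, that of 0.000576637 moved 6 and kept 6, and voom moved 7 and kept 5. With the 25th-percentile pseudocount the XUT medians were 1.31, 1.24, 0.859, 0.942, 0.587 and 0.606 (S288C, W303, SK1, SK1_2n, dcp2-7, upf1). With 0.000576637 they were 2.55, 2.62, 1.93, 2.79, 1.32 and 1.67 in the same order. Scaling by the mean log2 of snoRNAs gave 32 mRNAs lower in S288C, 4 lncRNAs in the dcp2-7 Terminator test and 4903 W303 differences. Models of the groups of one contrast gave 29 mRNAs lower in S288C, 15 in SK1_2n and 58 in upf1, 11 lncRNAs in the dcp2-7 Terminator test and 5127 W303 differences. The 25th-percentile pseudocount gave 9 mRNAs lower in W303 and 5 lncRNAs in the dcp2-7 Terminator test. With voom, chosen after seeing the data, these were 7 and 1, and the dcp2-7 minus xrn1 Terminator median was 1.45 (camera p = 0.00857 with the preset correlation). The antisense difference passed its threshold at 200 nt of overlap (0.33), with p = 0.564 with an estimated correlation. CAGE positions of dcp2-7 without a wild-type one numbered 1690 within 50 nt. Pairing replicates by number as a block gave 11 lncRNAs in the dcp2-7 Terminator test and 3326 lncRNAs higher in S288C, and of the gene lists 13 calls appeared, among them decapping factors and general stress genes in S288C (adjusted p = 0.0200 for each), and 7 ended.

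Leaving out one library at a time, with the lone sample of a group assumed to vary like the other groups, gave these ranges. In S288C lncRNAs higher were 3231 to 3268, mRNAs higher 5337 to 5379 and lower 12 to 15. In W303 they were 3064 to 3088, 5560 to 5602 and 10 to 11, in SK1 2442 to 2516, 5217 to 5322 and 49 to 64, and in SK1_2n 2834 to 2897, 5559 to 5590 and 16 to 24. In dcp2-7 they were 2101 to 2353, 3734 to 4889 and 51 to 134, and in upf1 2255 to 2484, 1981 to 2775 and 17 to 32. Strain differences were 1359 to 2418 (W303), 3294 to 4008 (SK1) and 6862 to 7224 (SK1_2n against SK1). The Terminator tests gave 2535 to 2674 lncRNAs in xrn1, 0 to 6 in dcp2-7, and a median of 1.15 to 1.40 between the mutants. XUTs higher in both upf1 and xrn1 were 1305 to 1427, and the antisense difference was 0.17 to 0.26.

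Of all class medians compared 116 kept their value within the replicate spread, 33 moved and 7 reversed. Of the counts and main values 377 stayed, 86 moved and 6 passed the threshold newly. The 41 gene list calls gave 164 comparisons, of which 101 kept the call, 57 lost it (39 with the estimated correlation) and 6 lost it with camera's direction turned, while 28 calls appeared in 220 comparisons of the other lists. Of the named features 1596 comparisons stayed, 13 lost their call and 1 reversed. Without chromosome 11, left out after seeing the data, all 7 values stayed, with 3113 lncRNAs higher in S288C. Not run were count tests with edgeR or DESeq2, because the table holds densities, and CAGE score thresholds, because the lists hold no score. Depth limits features near the floor, such as the wild-type SNO1 of S288C with 9 and 12 reads.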

Other observations

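Of the tests in this part, that on mRNAs opposite an XUT was set out before its result was seen, and no tests were chosen only after the result was seen. On the deposited scale 15, 15, 14 and 16 of the 19 mitochondrially encoded mRNAs rose in xrn1 S288C, W303, SK1 and SK1_2n, with medians of 0.50, 0.54, 0.73 and 0.96. In dcp2-7 17 rose (median 0.97), while in upf1 none rose and 1 fell (0.07). They were not tested as a group against other mRNAs.

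The 4 genes of the 2-micron plasmid had medians of 1.87, 2.90, 2.08 and 4.54 in the same xrn1 comparisons, 1.24 in dcp2-7 and 1.81 in upf1, where all 4 rose. Between the S288C wild types, WT_UPF1 against WT_S288C, all 4 were lower (median -1.21).

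A hypothesis of this work was that mRNAs with an XUT on the other strand rise less than others when Xrn1 is lost. In xrn1 S288C, 877 such mRNAs and 4549 others, without chromosome 11 and compared within classes of wild-type level, differed by -0.0112 (permutation p = 0.639, adjusted p = 0.747), so the expected lower rise was not seen. Only that value was predicted, and in the other comparisons the same difference was -0.0998 in SK1_2n (adjusted p = 0.0201), 0.0629 in SK1 and 0.0498 in dcp2-7 (adjusted p = 0.0485 for each), 0.0412 in W303 (adjusted p = 0.171) and 0.00733 in upf1 (adjusted p = 0.747).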
